A study of Drosophila melanogaster with 4 samples.

How the data were processed

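Targeted DamID was done on brains dissected from 3rd instar larvae, with the fusion proteins under GMR71C09-GAL4 and Gal80ts control. There were 4 samples with 3 biological replicates each, per the design text, namely Dam alone, Dam fused to full-length Prospero, Dam fused to a Prospero form named ΔN7, and Dam fused to HP1a. Per the labels' protocols, genomic DNA was cut with DpnI, which cuts only methylated GATC sites, ligated to adaptors, cut with DpnII and amplified by PCR. The product was sonicated, the adaptors were removed with AlwI, and sequencing libraries were made. Per the labels, the profile of each fusion was taken against Dam alone and averaged. Dam alone is thereby the background inside each profile, and the share of a gene's signal that comes from open chromatin cannot be recomputed from a list of names.

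The data analysed were 1 text table with 3 columns (gene name, FlyBase identifier and symbol) of genes with Prospero binding peaks, as the authors deposited it. It has no numeric column, no peak positions and no replicate values. The aligner, peak caller, threshold, rule for assigning peaks to genes and genome build are not given in the sources used here, nor is the Prospero form behind the list. A rule that assigns a peak to every gene within some distance would list several neighbours for 1 peak, and a threshold would set how many genes are listed. The separate profiles of full-length Prospero, ΔN7 and HP1a were not analysed here, so no overlap between profiles and no comparison of the groups was made. Sequencing depth is unknown, and no interval for it is given. Some entries may be missing from the table as analysed, so a gene described as not in the table is a gene not among the entries analysed here.

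The authors' deposited table held 1584 entries. Of these, 1512 carried a gene identifier and 72 a transcript identifier, and the transcript entries came from 54 gene names that all had a gene entry too. The gene entries gave 1510 unique identifiers. Names were matched to a RefSeq gene table of the Release 6 plus ISO1 MT assembly by current symbol (1457 entries) or by an older symbol or the authors' own name (50 entries), which matched 99.7% of the gene entries. In 7 entries the symbol was that of another fly species, and 6 of these were matched through the authors' name. The 5 unmatched entries were snRNA:U3:22A, ban, CG43189, CR45557 and 1 name that is only a number. The matched entries gave 1504 genes. Neighbours, arms and gene lengths (the span of the gene in that assembly) were taken from the same table as properties of genes, and no coordinates of it are printed.

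Before the data were examined, 20 gene lists, the tests, the naming rule and most alternatives were fixed. The background was all 13946 protein-coding genes on the chromosome arms. Each list was tested with Fisher's exact test, two-sided, with the conditional odds ratio, its exact 95% interval and Benjamini-Hochberg adjustment over the 20 lists, at an adjusted p of 0.05. Some lists share genes, with 23 genes in more than 1 list. Gene length was handled with the Mantel-Haenszel odds ratio over 10 length strata and an exact stratified test, two-sided. Length and arms were tested with 1e+05 permutations and neighbours with 10000. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only. Fisher's exact test treats genes as independent, which neighbouring genes are not, so the labels were also moved along the gene order through all 13946 positions. The naming rule took, per list, up to 8 members in the table and up to 5 not in it, in alphabetical order after the number of entries, and the 20 genes with the most entries.

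The alternatives chosen at that point were all annotated genes as background, length strata, 1 member per run of members within 10 kb, and each chromosome arm left out in turn. After the data were seen, 50 length strata, named genes only, no doubtful names, and the moved labels were added, as were comparisons of 6 pairs of lists and 5 further gene lists, which were also counted with 1 member per run and with the moved labels. The tests were checked on simulated lists of 30 genes among the 13946, with 200 draws each. With long members and no effect, the unstratified test called 60.5% of draws and the stratified test 3.5%. With members drawn from all genes and no effect, each called 2%. With a planted odds ratio of 8 in long members, the stratified median was 7.95 and 100% of draws were called. In these draws listing depended on the same length deciles that the stratified test uses, and each gene was drawn on its own. Runs of neighbouring listed genes and effects of length within a decile were not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.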

Results

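Binding of the homeodomain transcription factor Prospero was mapped in brains dissected from 3rd instar Drosophila larvae by targeted DamID. In this assay a bacterial DNA adenine methylase (Dam) is fused to a chromatin protein and expressed in chosen cells. GATC sites near the places where the fusion protein sits become methylated, and the methylated fragments are recovered with DpnI and sequenced. The fusion proteins were driven by the GMR71C09-GAL4 line under temperature-sensitive Gal80 control, and the series title places the profiles in neural precursors and neurons of the central brain. There were 4 samples, which were full-length Prospero, a Prospero form named ΔN7, the heterochromatin protein HP1a, and Dam alone as the background. The design text states 3 biological replicates for each. Prospero enters the daughters of neural stem cells (neuroblasts) and drives them out of division and into differentiation.

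The values analysed here are the names in 1 gene list, the genes that the authors' deposited table gives as holding Prospero binding peaks. It holds no peak height, position or value per replicate, so sequencing depth is unknown and no spread between replicates could be computed. The sources used here do not say which Prospero form the list came from, and the HP1a profile was not analysed here. Genes were compared with genes throughout, and the p-values measure association across genes of 1 list, not reproducibility between brains. Genes are identified by symbol and FlyBase identifier, and no positions are printed because the genome build behind the list is not given in the sources used here.

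The first question was which genes carried Prospero peaks. The authors' deposited table named 1510 unique gene identifiers, of which 1504 genes were matched to the reference annotation. Protein-coding genes made up 1082 of these, which is 7.76% of the 13946 protein-coding genes on the chromosome arms. The gene of the tagged factor itself, pros (FBgn0004595), was in the table. The fusions bring in Prospero coding sequence as well. Whether this entry reflects binding at the gene itself cannot be told from a list of names. It also counts among the listed members of the pan-neuronal differentiation list below. The gene that encodes HP1a was not among the entries analysed here. Among the other kinds of gene, 335 were long non-coding RNAs (16.8% of those annotated), 29 antisense RNAs (5.77%), 21 tRNAs (6.73%) and 18 microRNAs (6.87%). Only the first of these shares lay above that of protein-coding genes. The most entries per name, 4 each counting gene and transcript identifiers, belonged to the antisense RNAs asRNA:CR31429 and asRNA:CR43481 and the long non-coding RNAs lncRNA:CR31044 and lncRNA:CR33218. The number of entries counts identifiers and not peaks.

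The next question was which groups of genes the peaks fell on. Neuroblast identity factors stood highest of 20 gene lists fixed in advance, with 22 of 29 members in the authors' deposited table (75.9%, exact 95% interval 56.5 to 89.7) against 2.25 members expected from the share of all protein-coding genes. They included the proneural factor ase (FBgn0000137), dpn, a transcriptional repressor that maintains self-renewal (FBgn0010109), the Notch effector E(spl)mgamma-HLH (FBgn0002735), and the zinc finger factors erm (FBgn0031375), btd (FBgn0000233) and fru (FBgn0004652). The Sox factor D (FBgn0000411) and the translational repressor brat (FBgn0010300) were also among them. Some listed members stand in other lists as well and count there again, so the lists are not separate findings for these genes. They are brat and mira in asymmetric division, D, grh, opa and tll in temporal patterning, and N and E(spl)mgamma-HLH in Notch signalling. Others are l(1)sc in the optic lobe list and nerfin-1 in the pan-neuronal list. Of these, N, opa, tll and nerfin-1 were named after the table was seen. The neuroblast list is therefore not limited to factors that maintain neuroblasts. The members not in the table were ac, bam, esg, klu, pnt, sc and SoxN, of which sc and SoxN fell outside the naming rule and were named after the table was seen. The odds ratio was 38.1 (95% interval 15.7 to 106, Fisher's exact test, two-sided, adjusted p = 5.67e-18). Within deciles of gene length it was 25.3 (9.22 to 69.4, exact stratified test, adjusted p = 8.31e-15).

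Genes of temporal patterning, which give neuroblasts their age-dependent identity, were the next most often listed, with 15 of 25 members (60%, 38.7 to 78.9). They included the zinc finger factors cas (FBgn0004878) and chinmo (FBgn0086758), the ecdysone receptor EcR (FBgn0000546), the ecdysone-induced nuclear receptor Eip75B (FBgn0000568), and br, ey and grh. The early temporal factors hb and Kr and the late factors Eip93F and Eip74EF were not in the table. Imp and Syp, RNA-binding proteins that mark early and late neuroblasts, were in the table and were named after it was seen. The odds ratio was 18.1 (7.57 to 45.1, Fisher's exact test, adjusted p = 1.58e-10). Members of this list were long, with a median of 36409 bp, and within length deciles the odds ratio fell to 6.51 (2.82 to 15.05, exact adjusted p = 2.80e-05).

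Notch signalling and the Enhancer of split complex contributed 17 of 31 members (54.8%, 36.0 to 72.7). The ligand Delta (FBgn0000463) was listed together with the complex's basic helix-loop-helix repressors E(spl)m5-HLH, E(spl)m7-HLH, E(spl)m8-HLH and E(spl)mbeta-HLH. The Bearded-family members E(spl)m2-BFM, E(spl)m6-BFM and E(spl)malpha-BFM were also in the table. E(spl)m3-HLH and E(spl)m4-BFM of the same complex, the co-repressor gene H, and BobA and Brd were not in it. The odds ratio was 14.6 (6.77 to 32.2, Fisher's exact test, adjusted p = 7.38e-11) and 10.4 (4.76 to 22.6) within length deciles. Because the complex is a cluster of adjacent genes, the list was also counted with 1 member per run of members within 10 kb, which left 8 of 19 and an odds ratio of 8.77 (3.06 to 24.0, exact adjusted p = 0.000141). Without arm 3R, which carries the complex, the odds ratio was 5.93 (1.59 to 19.1, exact adjusted p = 0.0121), and without arm 3L it was 25.4 (10.2 to 68.6).

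Axon guidance and synaptic specificity genes were listed for 26 of 52 members (50%, 35.8 to 64.2). Among them were the netrin receptor fra (FBgn0011592), the cell surface protein Dscam1 (FBgn0033159), the receptor drl (FBgn0015380) and its relative Drl-2, the cytoplasmic kinase Abl and its partner ena, and the adhesion proteins caps and Con. The members beat-Ia, beat-IIIc, bdl, comm and dnt were not in the table. The odds ratio of 12.2 (6.75 to 21.9, Fisher's exact test, adjusted p = 7.12e-15) fell to 4.05 (2.26 to 7.27, adjusted p = 3.49e-05) within length deciles, in a list with a median gene length of 32650 bp.

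Pan-neuronal differentiation genes were in the table for 17 of 41 members (41.5%, 26.3 to 57.9). They included elav (FBgn0260400), the RNA-binding protein used as a general neuronal marker, the acetylcholine-synthesising enzyme gene ChAT (FBgn0000303), and acj6, a POU-domain factor. The cell adhesion genes CadN and Fas1, the synaptic release factor cpx, Appl and bru3 were listed as well. The active zone protein gene brp, the calcium channel gene cac, and dac, fne and jeb were not. The odds ratio was 8.54 (4.29 to 16.6, Fisher's exact test, adjusted p = 1.20e-08) and fell to 2.75 (1.47 to 5.17, adjusted p = 0.00622) within length deciles. In optic lobe and neuroepithelium genes, 12 of 25 members were listed, among them the eye and optic lobe factors ey, eya, Optix and Rx, the proneural genes ato and l(1)sc, and ap and fj. The odds ratio of this list was 11.1 (4.61 to 26.4, exact adjusted p = 3.00e-07) and 4.58 (1.999 to 10.5, adjusted p = 0.00104) within length deciles. It was 6.57 (2.21 to 17.8) without arm 2R and 21.0 (7.1 to 69.4) without arm 2L.

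Cell cycle genes were listed for 11 of 42 members (26.2%, 13.9 to 42.0). The members named by the rule were the cyclins CycA, CycB3 and CycE (FBgn0010382), the CycE/Cdk2 inhibitor dap (FBgn0010316), the replication licensing factor dup, the transcription factor E2f1, and fzr and fzy, which activate the anaphase-promoting complex. The mitotic kinase genes aurA and aurB, the checkpoint genes Bub1 and Bub3, and borr were not in the table. Unlike the neural lists, this list rose within length deciles, from an odds ratio of 4.25 (1.92 to 8.72, Fisher's exact test, adjusted p = 0.000757) to 6.38 (3.02 to 13.5, adjusted p = 0.000154), with a median gene length of 2869 bp.

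Asymmetric cell division genes and glial genes passed the test only without regard to gene length. For asymmetric division, 7 of 29 members were in the table, and these were brat, cnn, insc, mira, numb, stau and zip. They include mira, the adaptor that carries Prospero into the daughter cell, and the cell fate determinants numb and brat. The polarity genes aPKC, baz and dlg1 were not in the table, nor were aurA and Cdc42. The odds ratio of 3.8 (1.37 to 9.24, Fisher's exact test, adjusted p = 0.0142) was 1.93 (0.787 to 4.75, adjusted p = 0.309) within length deciles. It was 2.84 (0.832 to 7.83, exact adjusted p = 0.118) without arm 2L, 1.92 (0.362 to 6.53, adjusted p = 0.372) without arm 2R and 6.39 (2.15 to 17.3) without arm X. Of the glial genes, 7 of 31 were in the table, which were apt, the glutamate transporter gene Eaat1, the glial fate switch gcm (FBgn0014179), nrv2, Nrx-IV, pyr and ttk. The glial odds ratio of 3.48 (1.26 to 8.36, exact adjusted p = 0.0186) was 1.76 (0.748 to 4.17, adjusted p = 0.309) within length deciles. It was 2.16 (0.539 to 6.43, exact adjusted p = 0.233) without arm 2L and 3.04 (0.889 to 8.38, adjusted p = 0.0942) without arm 2R.

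**Figure D1:**
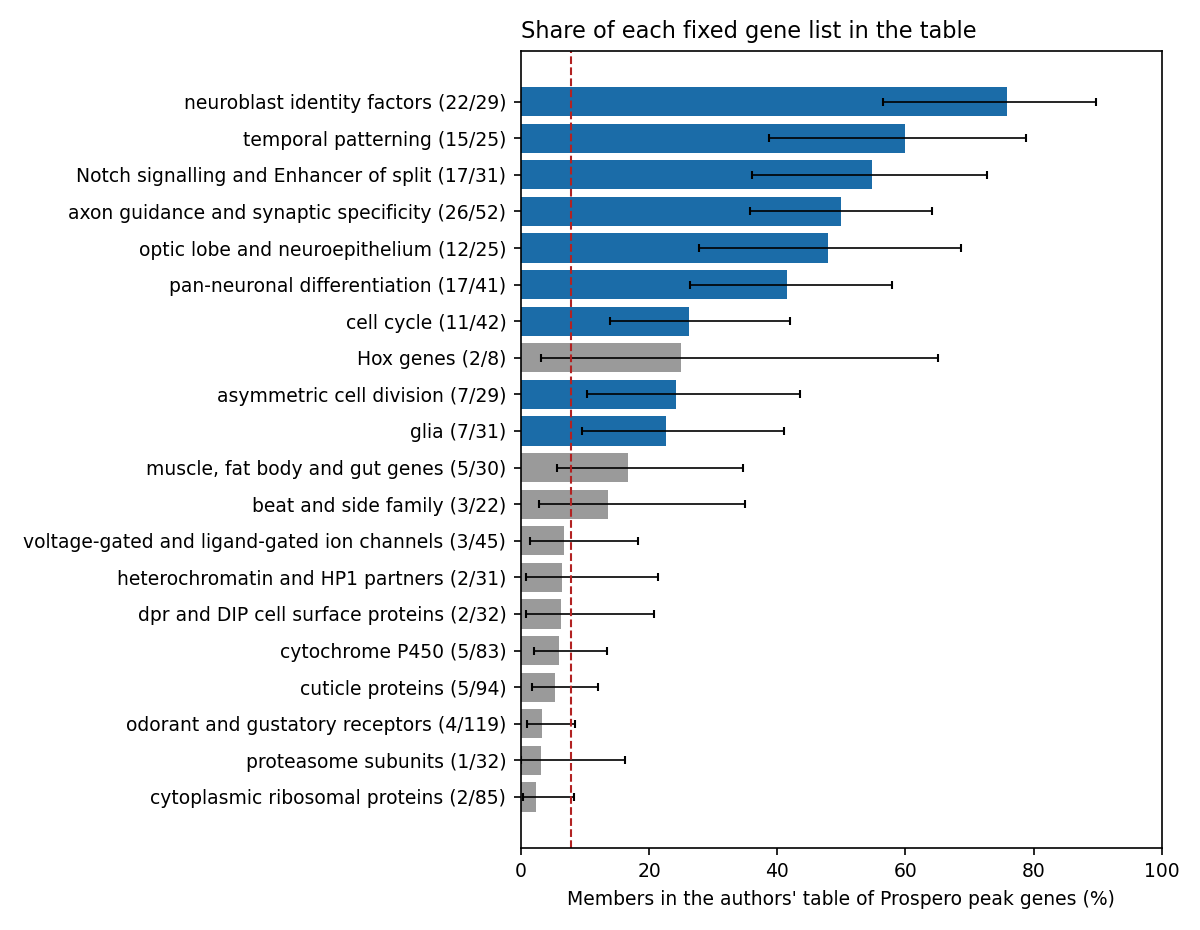
Share of the members of each gene list that are in the authors' deposited table, in percent, with exact 95% intervals; the numbers of listed and all members stand beside each name, and the dashed line is the share of all protein-coding genes (7.76%). Blue bars passed the adjusted test against all protein-coding genes and grey bars did not, from 22 of 29 neuroblast identity factors to 2 of 85 ribosomal protein genes.

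Several groups of genes were not over-represented. Of the genes for voltage-gated and ligand-gated ion channels, 3 of 45 were in the authors' deposited table (Grd, nAChRbeta2 and Nmdar2), while cac, eag and the calcium channel genes Ca-alpha1D, Ca-alpha1T and Ca-beta were not. The odds ratio was 0.849 (0.168 to 2.66, Fisher's exact test, adjusted p = 1) and 0.297 (0.0921 to 0.956, adjusted p = 0.0649) within length deciles. The dpr and DIP cell surface proteins had 2 of 32 members listed (dpr8 and dpr12), with an odds ratio of 0.792 (0.0916 to 3.13, exact adjusted p = 1) and 0.226 (0.0528 to 0.966, adjusted p = 0.0649) within length deciles. Within 50 length strata, a setting added after the data were seen, the ion channel genes (0.270, exact adjusted p = 0.0280) and the dpr and DIP genes (0.182, exact adjusted p = 0.0354) were listed less often than other genes of their length. The beat and side family had 3 of 22 (side, side-IV and side-V), with an odds ratio of 1.88 (0.356 to 6.4, exact adjusted p = 0.345) that turned to 0.502 (0.15 to 1.68) within length deciles. Heterochromatin genes and partners of HP1 had 2 of 31, His2Av and Kdm4B, with an odds ratio of 0.820 (0.0946 to 3.25, exact adjusted p = 1). Of the Hox genes, Antp and Ubx were listed (2 of 8, odds ratio 3.97, 0.391 to 22.2, exact adjusted p = 0.190), and within length deciles the odds ratio was 1.03 (0.202 to 5.20).

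None of the control lists from other tissues, sensory and detoxification families or housekeeping machinery passed the test against all protein-coding genes. Of the muscle, fat body and gut genes, 5 of 30 were in the table (Act57B, Col4a1, Fbp1, Lsp1gamma and Mlp84B; odds ratio 2.38, 0.711 to 6.36, Fisher's exact test, adjusted p = 0.138). Cytoplasmic ribosomal proteins had 2 of 85 members listed, RpL4 and RpS19b (odds ratio 0.285, 0.0339 to 1.07, exact adjusted p = 0.130), and without arm 3R none was left (upper bound of the odds ratio 0.709, adjusted p = 0.0281). Proteasome subunits had 1 of 32, Rpn8 (0.383, 0.00939 to 2.30, exact adjusted p = 0.683). Odorant and gustatory receptors had 4 of 119, Or42b, Or56a, Or67c and Or67d (0.411, 0.110 to 1.09, exact adjusted p = 0.138). Among named genes only, a background added after the data were seen, the ribosomal (0.226) and receptor (0.326) lists both passed the test as under-represented (exact adjusted p = 0.0345 for each). Within length deciles they moved towards 1, to 0.525 (0.129 to 2.14, exact adjusted p = 0.841) for ribosomal proteins and 0.739 (0.270 to 2.02, exact adjusted p = 0.965) for receptors. Cytochrome P450 genes had 5 of 83, Cyp12e1, Cyp28a5, Cyp4d20, Cyp6v1 and Cyp9b2 (0.761, 0.240 to 1.86, exact adjusted p = 0.804). Cuticle protein genes had 5 of 94, Ccp84Ab, Cpr100A, Cpr65Ay, Cpr65Az and Cpr66D (0.666, 0.211 to 1.62, exact adjusted p = 0.698). Both turned to values just above 1 within length deciles, 1.13 (0.454 to 2.82) and 1.04 (0.422 to 2.57).

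The lists were then compared with one another directly, in 6 pairs chosen after the shares were seen, with shared members left out. The p-values were adjusted over these 6 pairs only and do not allow for the choice among all pairs of lists. Neuroblast identity factors were listed more often than ion channel genes (odds ratio 40.4, 9.04 to 268, Fisher's exact test, two-sided, adjusted p = 3.87e-09). They were also listed more often than pan-neuronal genes (21 of 28 against 16 of 40, odds ratio 4.40, 1.40 to 15.3, exact adjusted p = 0.00634), cell cycle genes (8.54, 2.65 to 31.0, adjusted p = 0.000110) and asymmetric division genes (11.8, 2.96 to 57.3, adjusted p = 0.000110). Axon guidance genes were listed more often than ion channel genes (13.6, 3.64 to 77.3, exact adjusted p = 5.77e-06) and than the dpr and DIP genes (14.6, 3.15 to 138, adjusted p = 5.89e-05). The median gene lengths of the last 3 groups were 32650, 21373 and 32526 bp. All 6 differences stayed past the threshold within length deciles, with the largest exact adjusted p at 0.00479.

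**Figure D2:**
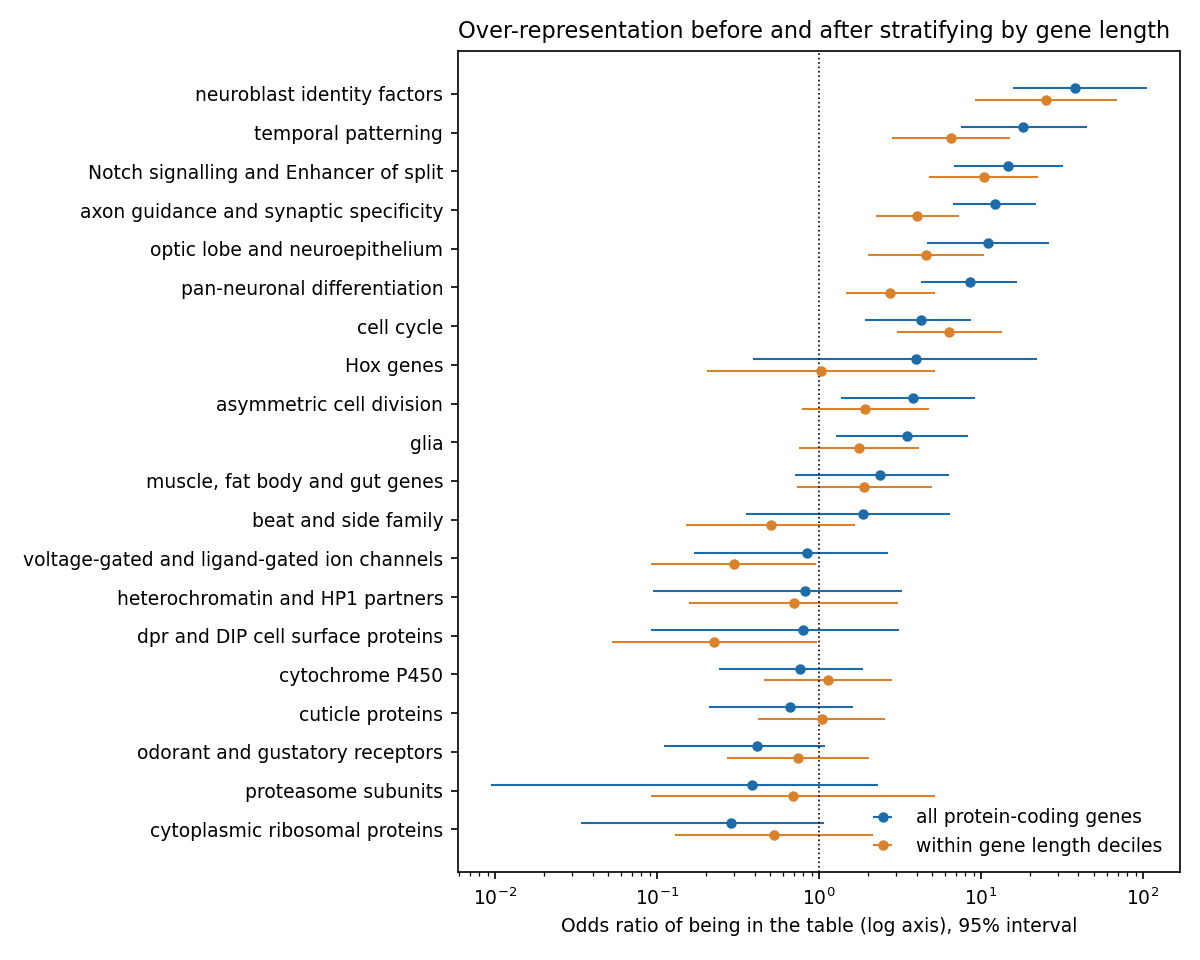
Odds ratio of being in the authors' deposited table for each gene list, on a log axis, with 95% intervals; blue points compare with all protein-coding genes and orange points compare within deciles of gene length. The neuroblast list stays highest (38.1 and 25.3), whereas asymmetric cell division and glia fall to 1.93 and 1.76 with intervals that reach below 1.

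Listed genes were long. The median length of the 1082 listed protein-coding genes was 6486 bp against 2066 bp for the others, a ratio of 3.14 (permutation test, two-sided, p = 1e-05, the smallest that the permutations can give). With non-coding genes included on both sides the ratio was 1.79 (permutation p = 1e-05). In the shortest decile of protein-coding genes 4.59% were in the authors' deposited table (exact 95% interval 3.55 to 5.82), and the share stayed under 7% up to the 8th decile. It was 12.5% (10.9 to 14.4) in the 9th and 26.3% (24.0 to 28.7) in the longest decile.

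**Figure D3:**
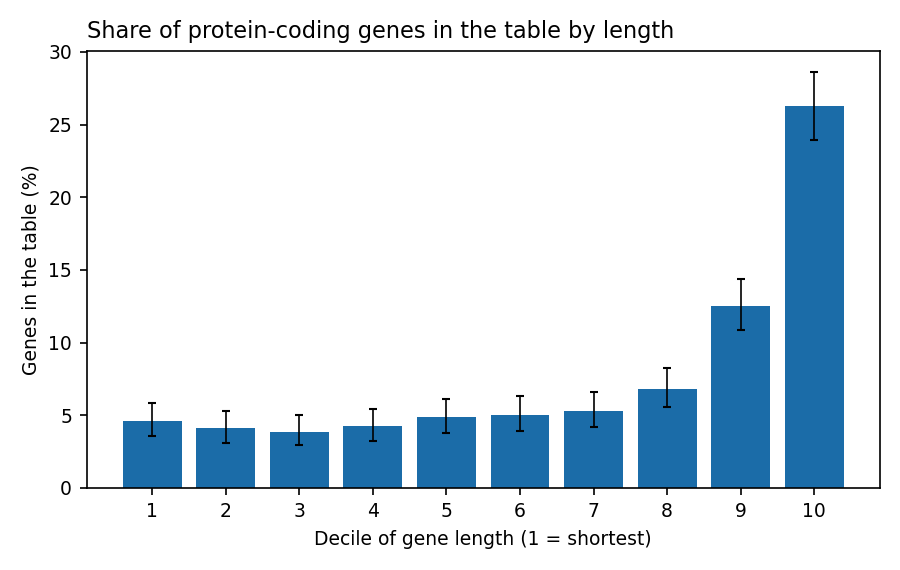
Share of protein-coding genes in the authors' deposited table, in percent, by decile of gene length from shortest (1) to longest (10), with exact 95% intervals. The share rises from 4.59% in the shortest decile to 26.3% in the longest.

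Prospero peak genes were spread over the chromosome arms with modest differences (chi-square 17.4, permutation p = 0.00578, and p = 0.00048 within length deciles). The only arms that passed the test were 3L and 2L. Arm 3L had 9.09% of its 2739 protein-coding genes listed (odds ratio 1.25, 1.07 to 1.45, Fisher's exact test, adjusted p = 0.0144). The share of arm 2L was 6.29% of 2657 genes (0.760, 0.637 to 0.903, exact adjusted p = 0.0101). The shares of 2R, 3R and X were 8.28%, 7.59% and 7.46%. On the small, heterochromatin-rich chromosome 4, 8 of 80 genes were listed (10%, odds ratio 1.32, 0.549 to 2.76, exact adjusted p = 0.564), and on Y none of 24 was. Within length deciles the odds ratio of chromosome 4 turned to 0.580 (0.267 to 1.26, exact adjusted p = 0.232). These tests treat genes as independent, and neighbouring genes were often listed together.

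Listed genes lay beside one another along the chromosomes. Of the 1082 listed protein-coding genes, 68.4% had a listed gene as the next protein-coding gene on one side or the other, against a mean of 14.9% (12.1 to 17.7) when the labels were permuted (permutation test, two-sided, p = 0.0002, the smallest that the permutations can give). Of the 1022 listed genes with any protein-coding gene within 10 kb, 70.7% had a listed one there, against 35.3% (31.7 to 38.9). The listed genes formed 615 runs, of which 342 were single genes with no listed neighbour. The longest held 10 genes on arm 3R, from Spn100A and Pka-C2 through the sterol-binding protein genes Npc2g and Npc2h to zfh1, a zinc finger homeodomain factor of the neuroblast list. The genes of this run were named after the table was seen. When the listed labels were moved along the gene order together, so that runs stayed whole, the same 9 gene lists passed the adjusted test, and no other position of the labels gave more than 12 neuroblast identity factors against the 22 observed. Other positions gave up to 9 asymmetric division genes and up to 10 glial genes, more than the 7 observed in each list. For cell cycle genes other positions reached the 11 observed. In the remaining lists that passed, no other position reached the observed count.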

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

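The tests of long non-coding RNA genes were chosen after their number in the table had been seen.

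The comparisons above used protein-coding genes, and a further signal stood outside them. The authors' deposited table held 335 long non-coding RNA genes, 16.8% of the 1995 on the arms, against 7.76% of protein-coding genes (odds ratio 2.40, 95% interval 2.09 to 2.74, Fisher's exact test, two-sided, p = 5.07e-34). A listed protein-coding gene lay within 10 kb of 250 of them (74.6%), so a candidate explanation is that both were assigned the same peak. Of all 1995 long non-coding RNA genes, 569 had such a neighbour, and 250 of these (43.9%) were listed. Among protein-coding genes with another listed one within 10 kb, 723 of 3386 (21.4%) were listed (odds ratio 2.89, 2.39 to 3.49, exact p = 4.18e-28). Among genes with no listed protein-coding gene within 10 kb, 85 of 1426 long non-coding RNA genes and 359 of 10560 protein-coding genes were listed, an odds ratio of 1.80 (1.40 to 2.30, exact p = 6.44e-06), which argues against sharing within that distance as the whole cause. Gene length argues the other way, since these genes are short (median 671 bp) and the odds ratio within length deciles was 3.97 (3.34 to 4.71). Sharing over longer distances and a difference between annotations stay open, and the design names no group that would test a biological explanation.

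The table also held 72 entries with transcript identifiers, from 54 genes that were each listed by a gene identifier too.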

How the results depend on the processing

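Of the odds ratios of the 20 lists under all alternatives, planned and added, 256 kept their direction and their side of the threshold. A further 8 lost the threshold, 5 gained it and 10 turned across 1. The settings of 50 length strata, named genes only, doubtful names left out and moved labels were added after the data were seen. Some of the 256 could hardly change. Moved labels keep the odds ratio and can change only the p-value, and no list has a member on arm Y. The run setting dropped no member of the neuroblast, asymmetric division, cell cycle, glia, Hox, optic lobe and proteasome lists. The number of over-represented lists fell from 9 to 7 within length deciles, within 50 strata and without arm 2L or 2R, and was 9 under every other alternative. For asymmetric cell division (3.8) the odds ratio was 1.93 within length deciles, 1.99 within 50 strata, 2.84 without arm 2L and 1.92 without 2R. For glia (3.48) it was 1.76, 1.64, 2.16 and 3.04 in the same order, and none of these 8 values passed the threshold. Within 50 strata ion channels (0.270) and dpr and DIP genes (0.182) passed it, while the Hox genes turned to 0.961. Ribosomal proteins passed it without arm 3R (odds ratio 0, no listed member left) and among named genes only (0.226), as did odorant and gustatory receptors among named genes only (0.326), whereas within deciles and 50 strata both moved towards 1 (0.525 and 0.521, 0.739 and 0.732). Other lists turned across 1 without passing the threshold. The dpr and DIP genes gave 1.08 without 2L and 1.07 without 3R. The beat and side family gave 0.502 and 0.420, P450 genes 1.13 and 1.14, and cuticle genes 1.04 and 1.09, within deciles and 50 strata, and P450 genes 1.08 without 2R. The cause of these changes was not tested. Not run were GATC-site settings, exon length, a stricter peak threshold and overlap between profiles, which need a genome, exon lengths, peak values or a list per profile. The Hox list has no value without arm 3R, where no members are left. No paired analysis was possible because the list has no replicates.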

Other observations

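The gene lists in the next paragraph, the comparisons of control lists with other listed genes, the test of length for asymmetric cell division and glia, and the question of longer distances were chosen after the table was seen; the other tests of list and neighbour patterns had their predictions written before their results, though not before the list results themselves.

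For further gene groups, members of any list above were left out of the counts unless stated. Homeobox genes other than the 8 Hox genes were in the authors' deposited table for 24 of 64 members (odds ratio 7.27, 4.18 to 12.4, Fisher's exact test, two-sided, adjusted p = 1.09e-10). They included the motor neuron factors Lim3, eve and unc-4, the neural columnar factor vnd, the head factor oc, and B-H2, Lim1, pdm3 and zfh2. Members of the same kinds that were not in the table included the motor neuron factors exex and tup, the columnar factor ind and the head factor ems. Within length deciles the odds ratio was 4.20 (2.42 to 7.30, exact adjusted p = 3.96e-06). Polycomb and trithorax group genes, chromatin regulators that keep developmental genes off or on, had 14 of 39 members listed, among them Pc, Psc, Su(z)2, ph-p, ph-d, trx, Trl, kis and osa (6.73, 3.22 to 13.5, and 5.06, 2.41 to 10.6, within length deciles, exact adjusted p = 0.000251). Members of this group not in the table included E(z), Su(z)12, esc, Sce, pho, brm, mor, ash1 and ash2. The cell death genes grim, hid, skl, Diap1, Dcp-1 and Decay made up 6 of 16 apoptosis genes (7.17, 2.14 to 21.8, and 8.04, 2.77 to 23.3, exact adjusted p = 0.00107). Nuclear receptors had 6 of 17 listed, including Hr4, Hr39, Hr51 and eg, and did not pass within length deciles (2.73, 0.99967 to 7.48, exact adjusted p = 0.0512). With the temporal and neuroblast factors EcR, Eip75B, svp and tll counted too, 10 of 21 were listed and the group passed (4.47, 1.84 to 10.9, exact adjusted p = 0.000957). With the labels moved along the gene order, which keeps runs of listed genes whole, the homeobox, Polycomb and trithorax, apoptosis and nuclear receptor lists passed (adjusted p from 0.000359 to 0.00359 over all positions, an exact test). Other positions gave up to 8 apoptosis genes and 7 nuclear receptors, more than the 6 observed in each. They gave at most 16 homeobox genes against 24 observed, and 12 Polycomb and trithorax genes against 14. With 1 member per run of members within 10 kb, the odds ratios of these lists lay between 6.25 and 8.20. That setting dropped none of the 17 nuclear receptors or 16 apoptosis genes, so it was no check on those lists. Oxidative phosphorylation subunits had 8 of 80 listed (1.32, 0.549 to 2.76, exact adjusted p = 0.403) and gave 2.25 (1.06 to 4.77, exact adjusted p = 0.0574) within length deciles, which did not pass.

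Technical explanations were weighed for the over-represented lists of neural genes. For asymmetric cell division, gene length took the odds ratio from 3.8 (1.37 to 9.24) to 1.93 (0.787 to 4.75), and for glia from 3.48 (1.26 to 8.36) to 1.76 (0.748 to 4.17), so both calls ended with intervals that hold 1 as well as the earlier value, and length stays open as their cause. The neuroblast identity, temporal patterning, Notch, pan-neuronal, axon guidance and optic lobe lists each stayed past the threshold within length deciles, with adjustment over all 20 lists and the lowest odds ratio at 2.75. This argues against length as the whole cause for these 6. The stratified test treats genes as independent, however, and no setting handled gene length and runs of listed genes together. For the same 6, the lowest odds ratio was 7.53 with 1 member per run and 6.85 among genes with a name other than a CG number. Peaks shared by members within 10 kb are thus not the whole cause, and neither is the presence of CG-numbered genes in the background. The run setting dropped no member of the neuroblast and optic lobe lists, and sharing over longer distances was not tested. Having a name is only a rough measure of how well a gene is studied, so that explanation stays open. A remaining hypothesis is that genes of these 6 lists may be Prospero targets, but accessibility to Dam, the peak threshold and the Prospero form were not tested here.

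Neighbouring listed genes are the other pattern. The 68.4% with a listed next gene compares with 15.5% (12.7 to 18.5) when labels were permuted within length deciles, so length is not the cause. Among 340 listed genes with a next gene more than 10 kb away on at least one side, 44.4% had a listed gene there against 11.1% (5.53 to 17.2). Sharing between genes at most 10 kb apart is thus not the whole cause. The 10 kb is the gap between genes, so a peak lying between genes farther apart could still list both. Runs of 3 or more held 39.0% of listed genes, and whether 1 peak listed several genes over longer distances cannot be told apart from separate peaks, since the assignment rule is not given in the sources used here.

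That control genes may stand in the table through a neighbour was tested and stays open. Of 22 listed members of the 6 control lists, 19 (86.4%) had a listed neighbour that shares no list with them, against 46 of 100 for the 6 neural lists that held within length deciles, an odds ratio of 7.33 (1.97 to 41.1, Fisher's exact test, two-sided, p = 0.00069). Against the 960 listed genes of neither kind of list, of which 69.2% had a listed neighbour, the control members did not pass the test (odds ratio 2.82, 0.821 to 14.997, exact p = 0.102), while the neural members were lower (0.380, 0.245 to 0.589, exact p = 5.97e-06). With neighbours of a shared list counted, the shares were 90.9% for control and 56% for neural members (odds ratio 7.75, 1.73 to 72.0, exact p = 0.00281), and neural members against genes of neither kind gave 0.568 (0.366 to 0.884, exact p = 0.00939). All these comparisons treat genes as independent and take no account of gene length. Median gene lengths ran from 873.5 to 2958.5 bp over the control lists and from 2689 to 36409 bp over the neural lists.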
